A study of Mus musculus with 6 samples.

How the data were processed

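RNA of 3 kinds of cultured mouse cells was measured on 6 Agilent oligonucleotide arrays, 2 per kind: multipotent adult progenitor cells (MAPC), embryonic stem cells (ESC) and neurospheres (NS). Each array was hybridized with Cy3-labelled sample and a common Cy5-labelled reference RNA from 11 mouse cell lines, and the dyes were not swapped. Per the labels the series holds 2 biological replicates of each kind. The labels describe both MAPC arrays with the same clone, so p-values that involve MAPC measure the spread between these samples and not the spread between clones.

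The deposited scanner files hold, for each spot and dye, the mean intensity and the median intensity of the local background, as read by Agilent Feature Extraction A.7.5.1 per the file headers. They also hold the authors' background-subtracted intensity and a processed intensity that Feature Extraction had normalized between the dyes, which served as an alternative here. The deposited series matrix holds 1 column per array in log10 units, with column medians from 2.95 to 2.97. Its rule is not given in the sources used here and was worked out from the values. Of its 41034 probe spots, 1488 had a value at a floor of 2 (log10) and 39546 did not. For 90.1% of the latter the column equalled the deposited log10 ratio of sample to reference processed intensity plus a constant of the spot, to within 0.001, and for 91.6% that constant was the spot's mean log10 reference intensity. Scale and direction are therefore known for those spots. Centring and the rule for the other spots stay unknown. The matrix repeats the processed intensities almost value for value and is not separate evidence. Columns of per-sample values left without a sample numbered 0.

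Signals were corrected for background with normexp (offset 50) and normalized within each array by loess in limma 3.58.1 under R 4.3.3, with files read by the R package data.table (version 1.17.8). Values are log2 ratios of sample to reference. Control spots and spots marked as outliers were left out, and spots of 1 probe were averaged. Of the genes named, this left 1 measured array for B2m in ESC and in NS, Zfp42, Gpm6b, Pdk1 and Sparcl1 in NS, and Lama1 and Ptprs in MAPC. Gene names came from a RefSeq gene table that pairs accessions with symbols: of 41006 probes, 15294 were named through an accession, 23 through a symbol, 112 through an older symbol, and 25577 stayed unnamed and were tested under their accession. Where a gene had several probes, which held for 2808 of 12362 symbols, the probe with the highest mean intensity was used. A gene was tested if its probe was well above background in the sample channel on both arrays of at least 1 group, by Feature Extraction's own mark, which left 35771 genes, 12150 of them named. That mark is weak evidence that a transcript was present, since between 90.3% and 99.5% of 797 olfactory receptor probes carried it on an array. No depth applies to arrays, and the number of arrays limits the precision.

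The contrasts MAPC minus ESC, MAPC minus NS and ESC minus NS were tested in a single limma fit (lmFit and eBayes, two-sided) of all 6 arrays with 3 residual degrees of freedom. Adjusted p-values are Benjamini-Hochberg values within a contrast, with a threshold of 0.05, and errors are moderated standard errors (SE) of the difference. Profile distance is the root mean square over genes of the difference of group means. With 2 arrays per group no permutation of the arrays can reach the threshold. The contrasts against MAPC share the MAPC arrays, so the overlap of their calls was set beside 100 simulations of unchanged groups and beside the overlap of independent lists.

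Gene lists were tested with limma's camera (preset correlation 0.01 between genes) on 18 lists in 3 contrasts, adjusted over the 54 tests, and again with a correlation estimated from the arrays and with fry, which tests a list without comparing it with other genes. The estimated correlation rests on 3 residual degrees of freedom, so a list not called with it is not thereby shown to be unshifted. The lists were pluripotency, primitive endoderm and its derivatives, trophoblast, gastrulation and early mesoderm, neural progenitor, neurons, astrocytes and oligodendrocytes, hematopoietic stem and progenitor, mature blood and macrophages, mesenchymal and fibroblast, endothelial, bone, cartilage and fat, cell cycle, hypoxia response and glycolysis, cholesterol synthesis, class I antigen presentation by the major histocompatibility complex (MHC), imprinted genes and Hox. A further list of sex-linked genes had 3 measured members, under the 5 that camera was given at least, and was only counted. Counts, medians and means cover all measured members, while camera and fry used members with a value on every array. Of 466 list genes, 363 had a named probe. Nanog, Gata4, Gata6, Kdr, Eng, H2-K1 and Itgb1 had none and are not analysed here.

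Genes were named by a rule. Among named genes past the threshold whose arrays did not overlap between the groups, it took the 8 with the largest fold each way, and the 5 each way with the largest lower bound where a gene was not well above background on either array of the lower group. It added up to 4 members of each list, a fixed set of key genes whatever their result, and the 8 genes each way that differed most from both others in MAPC. Members of a list were open to naming with their values. Some genes that the rule covers are counted but not reported here by name. A bound, printed as at least N-fold, sets the mean of the brighter group against the dimmer group's own signal or the lowest signal well above background on the array, whichever is higher. It comes from the sample channel after loess and Aquantile, without the reference, so it can exceed the fold of the log ratios. An adjusted p printed beside a bound belongs to the limma test of the log ratios, and the bound itself was not tested. Signed values and orders use the log ratios. These bounds and all folds are open to dye bias, since the dyes were not swapped. The tests, lists, naming rule and most alternatives were chosen before the data were examined.

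Replicate number and the day of image extraction coincided: replicate 1 of every group was extracted on one day and replicate 2 on another. The contrasts were therefore also computed within each day and with replicate number as a term of the fit. The files used hold no scan date, so none was used as a term. The deviations of replicates 1 and 2 correlated across genes by 0.101 between MAPC and ESC, 0.162 between MAPC and NS and 0.207 between ESC and NS.

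The pipeline was tested on simulated data with 200 changed genes among 35771. With spreads drawn from the fitted prior, it recovered 84.2% of 1.5-fold, 98.4% of 2-fold and 100% of 4-fold changes for MAPC minus ESC, and unchanged genes made up 5.08% of its calls. For MAPC minus NS the shares were 85.0%, 98.0% and 99.8%, with 4.92% unchanged, and for ESC minus NS 85.4%, 98.7% and 99.8%, with 5.27%. With each gene's moderated spread, which is less variable than a true one, unchanged genes made up 9.10%, 8.60% and 9.05% of the calls. A shifted list was recovered each time, and 0 of the 17 other lists were called. Genes were simulated independently of each other, so this does not show how often lists of correlated genes are called falsely.

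Alternatives covered the background correction, the normalization within and between arrays, the sample channel alone, the deposited processed intensities, the series matrix, the filter, the choice among probes, the groups in the fit, the prior, array weights, the replicate term, the threshold, and each array left out in turn. A filter on the negative control spots and a fit of named genes alone were chosen after seeing the data. Ranges of adjusted p over the alternatives leave out fry and the estimated correlation. Leaving out an array of the group outside a contrast gave the same result as fitting the 2 groups of that contrast alone.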

Results

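The arrays compared 3 cultured mouse cell types, with 2 arrays each. MAPC are adherent cells grown out of bone marrow. The clone used here, described in the labels as high in Oct4 (the protein of Pou5f1), came from marrow depleted of CD45- and Ter119-positive cells after 4 weeks and plated at 10 cells per well. It had passed more than 80 population doublings in 5% oxygen with 2% serum, epidermal growth factor, platelet-derived growth factor and leukemia inhibitory factor (LIF). ESC were C57BL/6 embryonic stem cells kept on irradiated embryonic fibroblasts with 15% serum and LIF, and were plated without feeders before RNA was taken. NS were neurospheres, floating clusters of neural progenitors, from the forebrain of C57BL/6 embryos, grown with fibroblast and epidermal growth factors. The series concerns blood formation by MAPC, and the arrays set MAPC beside a pluripotent and a neural stem cell. Culture conditions differed along with the cell type, so cell type and culture cannot be told apart in any comparison below.

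Between 91.9% and 99.6% of the 41034 probe spots were well above background in the sample channel. The number of arrays limits the precision of every value below. MAPC lay 0.658 log2 units from ESC (root mean square over genes) and 0.786 from NS, and ESC lay 0.651 from NS. The arrays of a group lay 0.128 apart in MAPC, 0.147 in ESC and 0.109 in NS, so each distance between groups exceeded the spread between replicates. Across genes, which are not independent replicates, arrays correlated by 0.583 to 0.604 between MAPC and ESC, 0.444 to 0.457 between MAPC and NS, and 0.571 to 0.584 between ESC and NS.

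**Figure D1:**
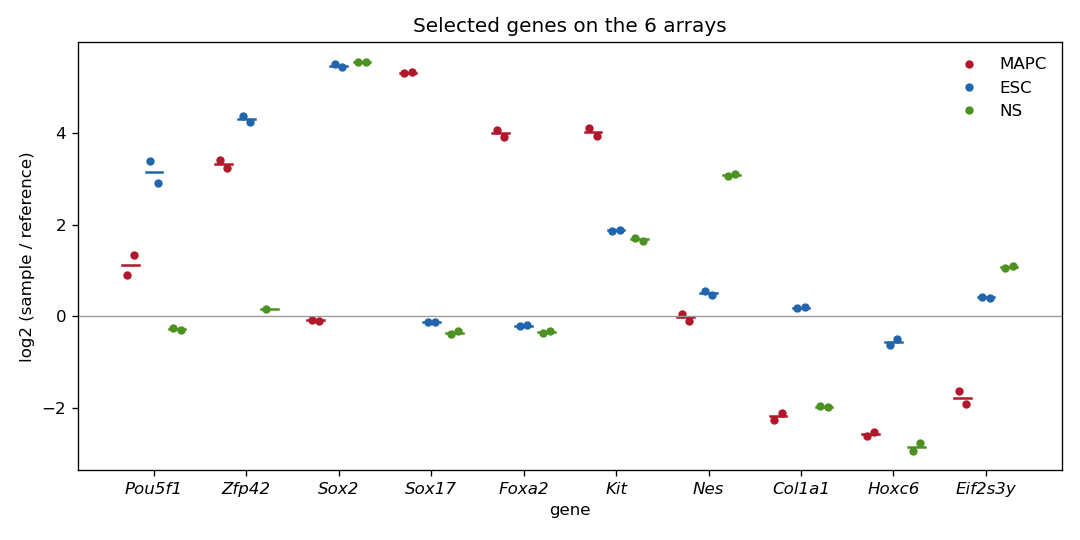
Log2 ratio of sample to reference (vertical axis) for 10 genes on each array, with 1 point per array, colours for MAPC, ESC and NS, and a line at each group mean; Zfp42 has 1 NS point because its other spot was marked as an outlier. MAPC lie at a mean of 5.31 for Sox17, against -0.12 in ESC and -0.35 in NS, and at -0.09 for Sox2, against 5.47 in ESC and 5.55 in NS.

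The comparison of MAPC with ESC asks which genes separate the marrow-derived clone from pluripotent cells. MAPC held higher transcript levels of most genes listed for the primitive endoderm, the embryonic layer that forms the yolk sac lining. They held lower levels of most pluripotency genes, Sox2 among them, although some genes of that list stood level or higher. Most genes of the mesenchymal and fibroblast list were also lower in MAPC than in ESC. With an estimated correlation camera called none of these 3 lists (adjusted p from 0.0918 to 0.121). Of 35771 genes, 13629 passed the threshold in limma, 5722 higher and 7907 lower in MAPC, and 3065 of them differed at least 2-fold (1054 higher, 2011 lower).

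Of the 21 measured primitive endoderm genes, 14 were higher and 3 lower in MAPC, with a median log2 difference of 2.11 (camera adjusted p = 4.28e-08, and adjusted p = 0.0918 with an estimated correlation). Sox17, an endoderm transcription factor, was higher by 5.44 ± 0.0523 (log2 ± SE, n = 2 arrays per group, adjusted p = 7.83e-09). Srgn, the core protein of a secretory granule proteoglycan, was higher by 5.78 ± 0.0946 (adjusted p = 2.16e-08). The transcription factors Foxa2 and Sox7 were higher by 4.20 and 4.15, the receptor Pdgfra by 3.00, and the basement membrane genes Lamc1, Col4a1 and Lamb1 by 2.36, 2.17 and 1.67. Apoe, a lipid carrier, was lower (-3.81), and the hepatocyte factor Hnf4a (-0.04) and Apoa1 (0.04) did not pass. Lama1 was lower by its brightest probe (-2.39) and higher by another (2.47), so its direction is unsettled.

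Of 24 pluripotency genes, 19 were lower and 2 higher in MAPC, with a median of -1.70 (camera adjusted p = 1.05e-08, and adjusted p = 0.121 with an estimated correlation). Sox2 was lower by -5.56 ± 0.0531 (adjusted p = 7.83e-09), and by -9.15 in the sample channel alone. Its background-subtracted signal on the MAPC arrays (10.6 and 17.9) lay below the highest negative control spot (39.9 and 165). It lay above 98.4% and 99.7% of the control spots. The size of the Sox2 difference depends on the background correction. The nuclear receptor Nr0b1 and the Ras-like gene Eras were lower by -4.95 and -4.49. Dppa3 and Gdf3 were not well above background on either MAPC array and were at least 74.4-fold and at least 33.3-fold lower (adjusted p = 2.51e-08 and 2.83e-08). Pou5f1, which encodes Oct4, was lower by -2.02 ± 0.175 (adjusted p = 5.21e-05, and -1.80 on its other probe). Zfp42, also called Rex1, was lower by -0.98 ± 0.0808 (adjusted p = 1.01e-04), a call that the deposited processed intensities did not give (-0.25, adjusted p = 0.312, with adjusted p from 2.21e-05 to 0.782 over the alternatives). The germline gene Dppa5a (0.09) and the methylation cofactor Dnmt3l (-0.04) did not differ past the threshold, and Klf4 and Lin28a were higher, by 0.68 and 0.59.

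In the mesenchymal and fibroblast list, 21 of 23 genes were lower in MAPC and 1 was higher, with a median of -1.77 (camera adjusted p = 2.16e-11, and adjusted p = 0.0918 with an estimated correlation). The matrix gene Postn was at least 80.5-fold lower (adjusted p = 2.73e-07). Fbln2 (-3.27), the collagen crosslinker Lox (-3.13) and Col1a1 (-2.37) were lower, and Vcam1, an adhesion molecule, was higher (1.35). Thy1 did not pass on its brightest probe (-0.09, adjusted p = 0.251), but its other probe gave -2.36 and the average of its probes passed (-1.23), with adjusted p from 8.49e-06 to 0.568 over the alternatives. Of 21 Hox genes 10 were lower and 1 higher, with a median of -0.22 (camera adjusted p = 0.00415, and adjusted p = 0.282 with an estimated correlation). Hoxa7 and Hoxa10 were lower by -2.02 and -1.04.

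Blood genes divided. Among 26 hematopoietic stem and progenitor genes 6 were higher and 8 lower, with a median of -0.04, a mean of 0.08 and a downward test (camera adjusted p = 0.885). Meis1, a partner of Hox proteins in stem cells, was higher by 2.31, the protein C receptor Procr by 2.17, Etv6 by 0.89 and Runx1 by 0.68. Kit, the stem cell factor receptor, was higher by 2.14 on its brightest probe, while its other probes gave 1.55 and -0.39. Ly6a (-2.14), Gata2 (-1.36) and Cd34 (-1.06) were lower, and Tal1 (-0.27, adjusted p = 0.0604), Lmo2 (-0.04) and the pan-leukocyte gene Ptprc (0.29, adjusted p = 0.141) did not pass. Tal1 passed with replicate number as a block (adjusted p = 0.0105) and in a fit of MAPC and ESC alone (adjusted p = 0.0435). Without ESC replicate 2 Tal1 differed by -0.36. It also passed with the processed intensities (-0.86) and in the sample channel alone (-0.90), within a range of 0.00778 to 0.743 over the alternatives. Ptprc passed in the fit of MAPC and ESC alone (adjusted p = 0.00994, range 0.00994 to 0.962 over the alternatives). Of 23 mature blood genes 10 were lower and 1 higher, with a median of -0.19 (camera adjusted p = 0.0286, and adjusted p = 0.296 with an estimated correlation). The lysozyme Lyz2 (-2.98, with -0.82 and -3.65 on its other probes) and the chemokine Ppbp (-2.15) were among those lower. The 16 endothelial genes had 6 higher and 6 lower, a median of -0.0036, a mean of 0.21 and an upward test (camera adjusted p = 0.735). The angiopoietin receptor Tek (2.06), Ramp2 (2.50) and Flt1 (1.55) were higher, and Pecam1 was lower (-0.76).

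MHC class I presentation was lower for 12 of 16 genes and higher for 2, with a median of -0.56 (camera adjusted p = 0.00180, and adjusted p = 0.179 with an estimated correlation). The class I light chain B2m was lower by -1.59, H2-Q10 by -2.05 and the interferon factor Irf1 by -2.02, and the chaperone Calr was higher by 1.27. Of 18 imprinted genes 10 were lower and 1 was higher, with a median of -0.30 (camera adjusted p = 0.00180, and adjusted p = 0.153 with an estimated correlation). They included the growth inhibitor Cdkn1c (-3.30), Snrpn (-2.52) and Ndn (-2.51), against Sgce (1.48). The Y-linked genes Ddx3y (-1.48), Eif2s3y (-2.19) and Uty (at least 1.53-fold, adjusted p = 0.000114) were all 3 lower.

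The neural progenitor list had 17 of 32 genes lower and 2 higher, with a median of -0.30 (camera adjusted p = 0.00213, and adjusted p = 0.178 with an estimated correlation). It was led by Sox2, which it shares with pluripotency, and the head factor Otx2 (-2.97), with Nes at -0.53 (adjusted p = 0.000481) and Pax6 at -0.29 (adjusted p = 0.00330). The call on Nes was lost in the sample channel alone (range 0.000221 to 0.0887 over the alternatives) and that on Pax6 without background subtraction (range 0.000795 to 0.265). Vim (-0.16, adjusted p = 0.442) passed, of the alternatives, only without ESC replicate 1 (-0.42, adjusted p = 0.00328). Of 25 cell cycle genes 13 were lower and 5 higher, with a median of -0.25 (camera adjusted p = 0.0286, and adjusted p = 0.207 with an estimated correlation). Cyclin D1 (Ccnd1, -2.92, and -0.48 on its other probe) and cyclin E1 (Ccne1, -1.20) were lower. The call ended without MAPC replicate 1 (adjusted p = 0.120) and without ESC replicate 1 (adjusted p = 0.0765), within a range of 0.0118 to 0.468 over the alternatives. Hypoxia and glycolysis genes were not called as a list (7 higher, 14 lower of 25, median -0.33, camera adjusted p = 0.311), with the pyruvate dehydrogenase kinase Pdk1 at -4.40 and the collagen hydroxylase P4ha2 at 2.71. Trophoblast genes (3 higher, 4 lower of 12, median -0.11, camera adjusted p = 0.651) held the simple-epithelium keratins Krt8 (3.60) and Krt18 (2.71) against Tfap2c (-3.14). Gastrulation genes (3 higher, 7 lower of 19) had a median of 0.02, a mean of -0.35 and a downward test (camera adjusted p = 0.632), with the Nodal antagonist Lefty1 at -5.68, Snai1 at 1.94 and T, or brachyury, at 0.11 (adjusted p = 0.164). The average of the probes of T was called in the other direction (-0.32, range 0.00206 to 0.709 over the alternatives). Neurons (1 higher, 5 lower of 15, median -0.09, camera adjusted p = 0.183) and bone, cartilage and fat (1 higher, 5 lower of 17, median -0.05, camera adjusted p = 0.278) were not called, and neither was cholesterol synthesis (3 higher, 6 lower of 14, median -0.18, camera adjusted p = 0.440). Astrocytes and oligodendrocytes (3 higher, 4 lower of 13) had a median of -0.07, a mean of 0.07 and a downward test (camera adjusted p = 0.632). Alpl, of the bone, cartilage and fat list, stood at -0.05 on its brightest probe. Its other probe gave -5.25, and also -3.22 in MAPC minus NS and 2.03 in ESC minus NS.

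Beyond the lists, the hexokinase-like gene Hkdc1 (5.38), Lhfpl1 (5.48), the magnesium channel Trpm6 (4.75), Glipr1 (4.67), the BMP-binding Bmper (4.52) and the secreted lectin Chil3 (4.23) were higher in MAPC. Pla2g12b, a phospholipase-like gene with a part in lipoprotein secretion, was at least 70.2-fold higher (adjusted p = 7.83e-09), and Hdc, which makes histamine, at least 3.20-fold (adjusted p = 0.000183). Lower in MAPC were the activin subunit Inhba (-5.79), the germ cell gene Morc1 (-5.51), Col18a1 (-5.44), Igfbp2 (-5.44), the neuronal Stmn2 (-5.31) and Tcea3 (-5.05). Adjusted over the list alone, the counts equalled those over all genes except in neural progenitors (4 higher, 18 lower), neurons (2 higher, 5 lower), hematopoietic (6 higher, 9 lower), endothelial (7 higher, 6 lower), cell cycle (8 higher, 13 lower), cholesterol synthesis (4 higher, 6 lower) and Hox genes (1 higher, 11 lower).

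With replicate number as a block, 14184 genes passed between MAPC and ESC, and the lists called stayed called, with camera adjusted p = 1.14e-07 for primitive endoderm, 4.10e-08 for pluripotency and 6.42e-11 for mesenchymal genes. Within extraction day 1 and day 2 the medians of these lists were 2.11 and 2.12, -1.54 and -1.77, and -1.77 and -1.79. The differences of the days correlated by 0.961 across genes. The other called lists had medians on days 1 and 2 of -0.35 and -0.29 (neural progenitor), -0.22 and -0.12 (mature blood), -0.26 and -0.35 (cell cycle), -0.48 and -0.62 (MHC class I), -0.23 and -0.35 (imprinted) and -0.37 and -0.19 (Hox).

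**Figure D2:**
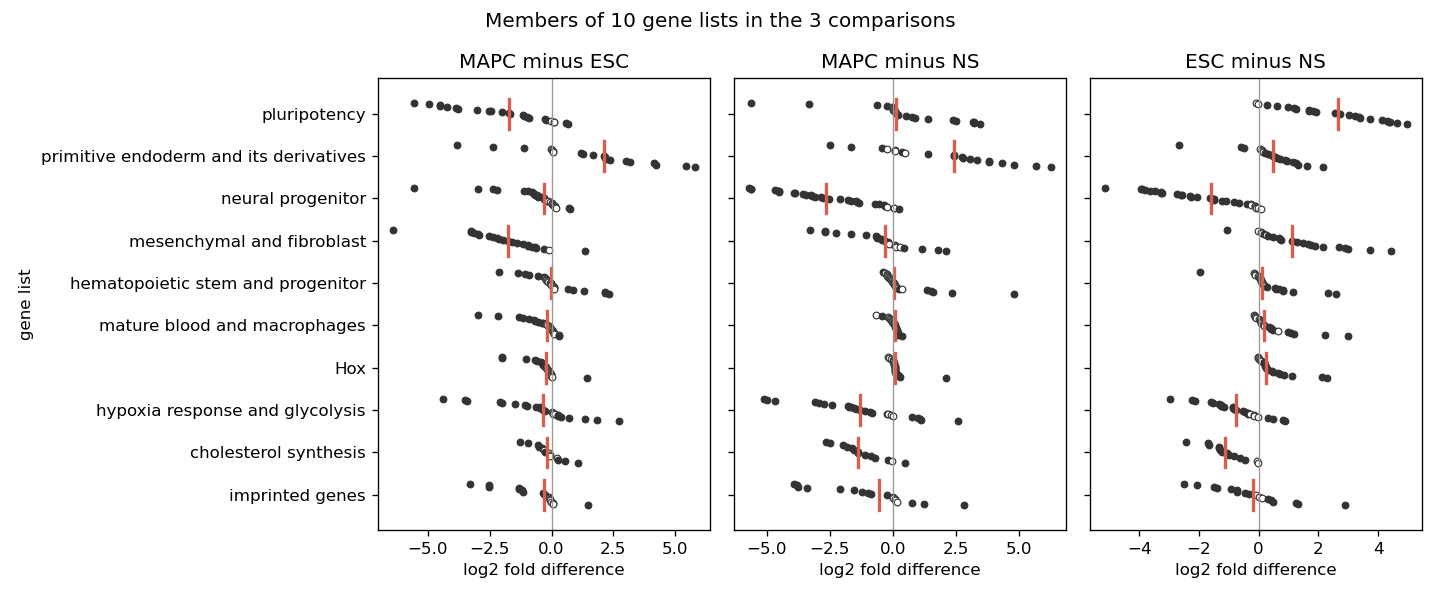
Log2 difference (horizontal axis) of each measured member of 10 gene lists in the comparisons MAPC minus ESC, MAPC minus NS and ESC minus NS, with 1 point per gene, filled where the limma adjusted p is below 0.05, and a bar at the list median. Primitive endoderm medians lie at 2.11 and 2.43 in the comparisons with MAPC and at 0.47 in ESC minus NS.

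The comparison of MAPC with NS sets the clone against a progenitor already committed to the nervous system. Endoderm genes were higher in MAPC here too, and so were the keratins Krt8 and Krt18 and part of the pluripotency list. Neural progenitor genes were lower in MAPC, and cholesterol synthesis and hypoxia genes were lower as well. Serum and oxygen are given for MAPC and not for NS, and culture cannot be separated from cell type here. None of the endoderm, neural progenitor, cholesterol and hypoxia lists was called with an estimated correlation (adjusted p from 0.0918 to 0.338). In limma 15654 genes passed, 7584 higher and 8070 lower in MAPC, and 4088 differed at least 2-fold (1587 higher, 2501 lower).

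Of 32 neural progenitor genes 28 were lower in MAPC and 1 higher, with a median of -2.64 (camera adjusted p = 2.89e-14, and adjusted p = 0.0918 with an estimated correlation). The receptor phosphatase Ptprz1 (-5.71), Sox2 (-5.64 ± 0.0531, adjusted p = 3.65e-09, and -9.78 in the sample channel alone, with MAPC near background) and the Notch target Hes5 (-4.68) were among the lowest. Nes, the intermediate filament nestin, was lower by -3.10 ± 0.0683 (adjusted p = 2.94e-08), Pax6 by -1.78 and Vim by -1.66. Of 15 neuronal genes 10 were lower and 2 higher, with a median of -0.46 (camera adjusted p = 0.00180, and adjusted p = 0.153 with an estimated correlation). The growth cone gene Gap43 stood at -3.98 and the tubulin Tubb3 at 1.95. Of 13 astrocyte and oligodendrocyte genes 8 were lower and 3 higher, with a median of -0.52 (camera adjusted p = 0.0283, and adjusted p = 0.296 with an estimated correlation). Aldh1l1 (-4.47) and Sox8 (-2.17) were the lowest.

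Primitive endoderm genes were higher for 14 of 21 and lower for 3, with a median of 2.43 (camera adjusted p = 3.38e-07, and adjusted p = 0.0918 with an estimated correlation). Srgn (6.25), Sox17 (5.67 ± 0.0523, adjusted p = 3.65e-09), Sox7 (4.78) and Foxa2 (4.33) led them, with the laminin gene Lamb1 at 3.82 and the anticoagulant receptor Thbd at 3.79. Lama1 again differed between probes (-1.66 and 3.20). Pluripotency genes were 11 higher and 4 lower of 24, with a median of 0.13 (camera adjusted p = 0.0612, not called). The list was called without MAPC replicate 2 (adjusted p = 0.0362) and without NS replicate 1 (adjusted p = 0.0306), within a range of 0.0175 to 0.149 over the alternatives. Pou5f1 was higher by 1.39 ± 0.175 (adjusted p = 0.000339) on its brightest probe and by 0.51 on its other. On replicate 2 its background-subtracted signal lay below the highest negative control spot in MAPC (163 against 165) and NS (59.1 against 69.1). It exceeded that spot on replicate 1 of both (121 against 39.9, and 53.4 against 30.5). On replicate 2 of both it lay above 99.7% of the 314 control spots, and it was marked well above background on every array. The size of the Pou5f1 difference still depends on the background correction, since these signals are low. Zfp42 was higher by 3.17, with 1 NS array measured, the methyltransferase Dnmt3b by 3.22, Dppa5a by 3.46 and Lin28a by 2.49, while Nr0b1 (0.02) and Eras (0.15) did not pass. Trophoblast genes were 4 higher and 0 lower of 12, with a median of 0.10 (camera adjusted p = 0.0136, and adjusted p = 0.197 with an estimated correlation). These were Krt18 (5.77), Krt8 (4.91), Phlda2 (2.81) and Gata3 (2.29).

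Among hematopoietic genes 6 were higher and 1 lower of 26 (median 0.03, camera adjusted p = 0.334). Procr (4.77), Etv6 (1.57) and Runx1 (1.51) were higher, as was Kit on its brightest probe (2.34, against 1.53 and -0.69 on the others). Meis1 (0.35), Gata2 (-0.22), Cd34 (-0.24), Ly6a (0.18), Tal1 (-0.15), Lmo2 (0.09) and Ptprc (0.12, adjusted p = 0.522) did not pass. In a fit of MAPC and NS alone Cd34 (adjusted p = 0.0179) and Gata2 (adjusted p = 0.0170) passed. Without NS replicate 1 Ptprc differed by 0.35. With the processed intensities Gata2 (-1.10), Cd34 (-0.57) and Tal1 (-0.50) passed at larger folds, as did Gata2 in the sample channel alone (-1.18) and Cd34 with scale normalization (-0.60). Over the alternatives adjusted p ran from 0.00861 to 0.962 for Gata2, 0.00441 to 0.815 for Cd34, 0.0365 to 0.820 for Tal1 and 0.00942 to 0.913 for Ptprc, so these results depend on the processing. Lmo2 was called in the other direction on the average of its probes (-0.26, range 0.00719 to 0.738). Mature blood genes (3 higher, 1 lower of 23, median 0.06, camera adjusted p = 0.632) included Lyz2 at 0.00. Endothelial genes (4 higher, 2 lower of 16, median 0.02, camera adjusted p = 0.521) included Tek (2.68) and Flt1 (2.21), with Pecam1 at 0.01 (adjusted p = 0.951).

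Cholesterol synthesis was lower for 12 of 14 genes and higher for 1, with a median of -1.39 (camera adjusted p = 4.60e-06, and adjusted p = 0.217 with an estimated correlation). Dhcr7 (-2.64), the last step of the pathway, and Fdps (-2.48) were the lowest. Hypoxia and glycolysis genes were 17 lower and 5 higher of 25, with a median of -1.30 (camera adjusted p = 0.000486, and adjusted p = 0.338 with an estimated correlation). The stress gene Ddit4 (-5.10), the peptide hormone Adm (-4.98) and Pdk1 (-4.67) were lower, and P4ha2 was higher (2.57). MHC class I genes were 11 lower and 2 higher of 16, with a median of -0.42 (camera adjusted p = 0.0143, and adjusted p = 0.217 with an estimated correlation) and B2m at -1.46. Imprinted genes were 10 lower and 3 higher of 18, with a median of -0.57 (camera adjusted p = 0.0114, and adjusted p = 0.197 with an estimated correlation). Among them were Ndn (-3.92), Peg12 (-3.81), Cdkn1c (-3.75) and, higher, Phlda2.

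Mesenchymal genes were 14 lower and 4 higher of 23, with a median of -0.32 (camera adjusted p = 0.0263, and adjusted p = 0.272 with an estimated correlation). That call ended without MAPC replicate 1 (adjusted p = 0.0839, range 0.00144 to 0.143 over the alternatives). Fbln2 was lower (-3.28), Postn was at least 5.77-fold lower (adjusted p = 1.84e-05), and Vcam1 (2.08) was higher, and Thy1 (0.08) did not pass. Col1a1 differed by -0.21 (adjusted p = 0.0268), a call lost without MAPC replicate 1 (adjusted p = 0.147), NS replicate 1 (adjusted p = 0.113) or NS replicate 2 (adjusted p = 0.0931). Hox genes (4 higher, 0 lower of 21, median 0.08, camera adjusted p = 0.296), gastrulation genes (4 higher, 4 lower of 19, median 0.08, camera adjusted p = 0.651), cell cycle genes (10 higher, 7 lower of 25, median 0.06, camera adjusted p = 0.620) and bone, cartilage and fat (1 higher, 4 lower of 17, median -0.04, camera adjusted p = 0.399) were not called. T stood at 0.21 (adjusted p = 0.0117), but at -0.03 when its probes were averaged, and its call was lost without MAPC replicate 2 (adjusted p = 0.0619) or NS replicate 1 (adjusted p = 0.0791). Cyclin D1 was lower by -4.22 on its brightest probe and by -0.86 on its other. Ddx3y (-2.17), Eif2s3y (-2.85) and Uty (at least 1.52-fold, adjusted p = 0.000138) were lower.

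Beyond the lists, the matricellular gene Ccn2 (7.14 ± 0.199, adjusted p = 8.27e-08), Glipr1 (6.40), Rpl39l (6.30), the coagulation inhibitor Tfpi (5.75) and the X-linked homeobox gene Rhox5 (5.68) were among the highest in MAPC, and Pla2g12b was at least 70.9-fold higher (adjusted p = 3.65e-09). The fatty acid carrier Fabp5 (-6.83 ± 0.0959, adjusted p = 6.99e-09), the adhesion receptor Adgrg1 (-6.20), the membrane proteolipid Gpm6b (-6.18), Kcnmb4 (-6.08), Igfbp2 (-6.00), Ptprs (-5.97, but -0.32 on its other probe) and Npdc1 (-5.91) were among the lowest. Lratd1 was at least 46.5-fold lower (adjusted p = 3.65e-09), followed by Hunk (at least 9.22-fold, adjusted p = 7.40e-08) and Cyria (at least 8.83-fold, adjusted p = 8.50e-09). Adjusted over the list alone, counts differed from those over all genes in primitive endoderm (15 higher, 3 lower), mature blood (1 higher, 1 lower), cell cycle (11 higher, 7 lower) and Hox genes (1 higher, 0 lower).

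With replicate number as a block, 16316 genes passed between MAPC and NS and the same lists were called, with camera adjusted p = 7.29e-14 for neural progenitors and 6.80e-07 for primitive endoderm. On days 1 and 2 the medians were -2.47 and -2.80 for neural progenitors, 2.62 and 2.44 for primitive endoderm, -1.43 and -1.34 for cholesterol synthesis and -1.24 on each for hypoxia. The other called lists had medians of 0.09 and 0.15 (trophoblast), -0.43 and -0.50 (neurons), -0.66 and -0.56 (astrocytes and oligodendrocytes), -0.25 and -0.39 (mesenchymal), -0.37 and -0.44 (MHC class I) and -0.56 and -0.58 (imprinted). The days correlated by 0.981 across genes.

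The comparison of ESC with NS serves as the reference contrast between a pluripotent and a neural stem cell. Most of the pluripotency list stood far higher in ESC, while Sox2 and Esrrb did not pass. Fibroblast, Hox and trophoblast genes were also higher in ESC, and neural progenitor, astrocyte and oligodendrocyte, cholesterol and hypoxia genes were higher in NS. None of these lists was called with an estimated correlation (adjusted p from 0.0918 to 0.282). In limma 13674 genes passed, 7093 higher and 6581 lower in ESC, and 3215 differed at least 2-fold (1688 higher, 1527 lower).

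Of 24 pluripotency genes 22 were higher in ESC and 0 lower, with a median of 2.65 (camera adjusted p = 2.89e-14, and adjusted p = 0.0918 with an estimated correlation). Nr0b1 (4.97), Eras (4.64), Dnmt3b (4.39), Zfp42 (4.15, with 1 NS array measured) and Pou5f1 (3.41 ± 0.175, adjusted p = 2.71e-06, and 2.31 on its other probe) were among them, Dppa3 was at least 75.2-fold higher (adjusted p = 2.71e-08), and Sox2 differed by -0.08 (adjusted p = 0.298), though without background subtraction by -0.26 (adjusted p = 0.0245). Neural progenitor genes were 24 lower and 0 higher of 32, with a median of -1.58 (camera adjusted p = 2.91e-14, and adjusted p = 0.0918 with an estimated correlation). Ptprz1 stood at -5.15, Hes5 at -3.94, Nes at -2.57 and Pax6 at -1.48. Nr2e1 was at least 2.75-fold lower (adjusted p = 2.00e-05). Astrocyte and oligodendrocyte genes were 8 lower and 1 higher of 13, with a median of -0.48 (camera adjusted p = 0.00299, and adjusted p = 0.217 with an estimated correlation). Aldh1l1 (-3.95) was the lowest of them. Neuronal genes (3 higher, 8 lower of 15) had a median of -0.26, a mean of 0.0034 and a downward test (camera adjusted p = 0.102), with Stmn2 at 3.69.

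Mesenchymal genes were 18 higher and 1 lower of 23 in ESC, with a median of 1.11 (camera adjusted p = 3.46e-08, and adjusted p = 0.121 with an estimated correlation). S100a6 (4.42), Postn (3.73), Lox (2.91) and Col1a1 (2.16) were higher. Thy1 stood at 0.17 on its brightest probe (adjusted p = 0.0382, range 1.02e-05 to 0.190 over the alternatives) and at 2.15 on its other. The call on the former was lost in a fit of ESC and NS alone, without ESC replicate 1 and without either NS array. Hox genes were 16 higher and 0 lower of 21, with a median of 0.25 (camera adjusted p = 0.000118, and adjusted p = 0.217 with an estimated correlation). Hoxc6 (2.28) and Hoxa7 (2.13) led them. Trophoblast genes were 8 higher and 0 lower of 12, with a median of 1.23 (camera adjusted p = 3.60e-05, and adjusted p = 0.121 with an estimated correlation). Tfap2c (3.07) and Krt18 (3.06) were the highest. Primitive endoderm genes were 14 higher and 3 lower of 21, with a median of 0.47 (camera adjusted p = 0.00154, and adjusted p = 0.153 with an estimated correlation). Lamb1 (2.15) led them, and Sox17 stood at 0.23, a direction the sample channel alone reversed (-0.41, adjusted p = 0.380) and a call lost without NS replicate 1 (adjusted p = 0.0709). Hematopoietic genes were 9 higher and 1 lower of 26, with a median of 0.11 (camera adjusted p = 0.0222, and adjusted p = 0.197 with an estimated correlation). Those higher included Ly6a (2.31), Gata2 (1.14) and Cd34 (0.82), with Tal1 (0.12) and Lmo2 (0.13) short of the threshold, although the average of the probes of Lmo2 was called in the other direction (-0.22, range 0.0169 to 0.819 over the alternatives). Kit stood at 0.20 on its brightest probe (adjusted p = 0.0585), with -0.31 and -0.02 on the others. The former passed with replicate number as a block (adjusted p = 0.0470) and in a fit of ESC and NS alone (adjusted p = 0.0327), within a range of 0.0303 to 0.713 over the alternatives. Mature blood genes were 9 higher and 0 lower of 23, with a median of 0.17 (camera adjusted p = 0.0106, and adjusted p = 0.266 with an estimated correlation). Lyz2 (2.98, with 0.91 and 3.86 on its other probes) and Ppbp (2.21) were the highest. Ptprc stood at -0.17 (adjusted p = 0.410) and passed without NS replicate 2 (adjusted p = 0.00617).

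Cholesterol synthesis genes were 12 lower and 0 higher of 14 in ESC, with a median of -1.13 (camera adjusted p = 1.59e-07, and adjusted p = 0.198 with an estimated correlation). Insig1, which restrains the pathway, stood at -2.45. Hypoxia genes were 17 lower and 4 higher of 25, with a median of -0.75 (camera adjusted p = 1.74e-05, and adjusted p = 0.282 with an estimated correlation). Adm (-2.96) was the lowest. Cell cycle genes were 16 higher and 5 lower of 25, with a median of 0.45 (camera adjusted p = 0.00213, and adjusted p = 0.153 with an estimated correlation). Cyclin E1 stood at 2.16 and Mcm5, part of the replicative helicase, at 1.15, while Ccna2 differed between its probes (-0.88 and 0.62). MHC class I genes were 6 higher and 2 lower of 16, with a median of 0.23 (camera adjusted p = 0.0347, and adjusted p = 0.265 with an estimated correlation). That call ended without ESC replicate 2 (adjusted p = 0.0501) and without NS replicate 2 (adjusted p = 0.0583), within a range of 0.00723 to 0.149 over the alternatives, and B2m (0.13) did not pass. Not called were imprinted genes (6 higher, 9 lower of 18, median -0.20, camera adjusted p = 0.257), endothelial genes (8 higher, 4 lower of 16, median 0.25, camera adjusted p = 0.373), gastrulation genes (6 higher, 2 lower of 19, median 0.08, camera adjusted p = 0.186) and bone, cartilage and fat (4 higher, 3 lower of 17, median 0.0046, camera adjusted p = 0.793). Lefty1 stood at 4.49, the bone matrix gene Spp1 at 3.99, Pecam1 at 0.77 (adjusted p = 0.00105), Vim at -1.49 and T at 0.11 (adjusted p = 0.158). T passed on the average of its probes (0.29) and without background subtraction, with adjusted p from 0.00306 to 0.605 over the alternatives, and Pecam1 was not called in the sample channel alone. Of the Y-linked genes, Ddx3y (-0.68) and Eif2s3y (-0.66) were lower in ESC, and Uty (0.06, adjusted p = 0.634) did not pass.

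Beyond the lists, Morc1 (5.70), Inhba (5.58), the small heat shock gene Hspb1 (5.58), Rhox5 (5.57), Ccn2 (5.25), the epithelial adhesion gene Epcam (4.95) and Rpl39l (4.69) were among the highest in ESC. Kcnmb4 (-5.40), the membrane proteolipids Gpm6a (-5.27) and Gpm6b (-5.17), Adgrg1 (-5.07), the protease inhibitor A2m (-4.86), Ramp1 (-4.83) and Sparcl1 (-4.65, and -2.58 on its other probe) were among the lowest. Adjusted over the list alone, counts differed from those over all genes in neurons (3 higher, 9 lower) and in astrocytes and oligodendrocytes (2 higher, 9 lower). With replicate number as a block, 14157 genes passed between ESC and NS and the same lists were called, with camera adjusted p = 1.09e-13 for pluripotency and 7.29e-14 for neural progenitors. On days 1 and 2 the medians were 2.69 and 2.47 for pluripotency, -1.68 on each for neural progenitors, 1.11 and 1.12 for mesenchymal genes, and 0.30 and 0.24 for Hox genes. The other called lists had medians of 0.54 and 0.39 (primitive endoderm), 0.93 and 1.19 (trophoblast), -0.52 and -0.50 (astrocytes and oligodendrocytes), 0.18 and 0.12 (hematopoietic), 0.17 and 0.13 (mature blood), 0.51 and 0.45 (cell cycle), -0.76 and -0.62 (hypoxia), -1.13 on each (cholesterol) and 0.28 and 0.22 (MHC class I). The days correlated by 0.969 across genes.

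Genes that set MAPC apart from both other cell types numbered 4109 higher and 4563 lower, of which 1888 and 1961 were named. Independent lists of the same sizes would share 1213 and 1784, and unchanged groups gave a mean of 0.05 and 0.09 in simulations. Neither benchmark tests how far MAPC stand apart. Both contrasts hold the same MAPC profile, which raises their overlap over independent lists, and unchanged groups give almost no calls. The overlap was not computed with a different MAPC array in each contrast, so its share due to shared arrays was not counted. The contrasts correlated by 0.604 across genes, against 0.50 in simulations of unchanged groups that share the MAPC arrays. Such a value near 0.50 arises there whatever the spread between arrays. The covariance of the contrasts was 0.311, against 0.00292 in those simulations. Spread between the shared arrays thus accounts for little of the covariance. Among the highest above both by log ratio were Srgn, Sox17, Hkdc1, Lhfpl1, Glipr1, Foxa2, the prostaglandin receptor Ptger3 (4.18 against ESC and 4.28 against NS) and Pla2g12b, which was not well above background in ESC or NS. Among the lowest below both were Sox2, Igfbp2, Npdc1 (-4.40 and -5.91), Pdk1, the axon guidance effector Dpysl3 (-4.00 and -4.34), the corepressor subunit Sap30 (-4.47 and -3.96), the prohormone-processing enzyme Cpe (-3.93 and -5.20) and Tmem131l (-3.91 and -5.04).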

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

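The tests weighed here on the reference channel were chosen after its result was seen. The reference channel carried the same RNA on every array, yet it showed differences that followed the cell types. Tested alone in limma after quantile normalization of the background-subtracted signals, it gave 51 genes past the threshold between MAPC and ESC, 106 between MAPC and NS and 54 between ESC and NS, against 8235, 11597 and 8413 in the sample channel treated in that way. At an unadjusted p under 0.05 it gave 3562, 5504 and 3055 genes. Over the 32901 genes compared, the covariance of the 2 channels between groups was 2.91, 4.95 and 2.55 times that from differences between arrays of a group, in the same order of comparisons. This argues against spot effects shared by both dyes as the whole cause, although replicate differences of the channels also correlated, by 0.770 in MAPC, 0.834 in ESC and 0.854 in NS. Cy3 signal read in the Cy5 channel is a candidate explanation: the reference rose with the sample more steeply in genes bright relative to the reference (slopes 0.166, 0.166 and 0.160) than in genes dim relative to it (0.0721, 0.0961 and 0.0887). Dim genes carry more noise, which may lower their slope. No biological explanation was tested, since the reference RNA was the same.

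A signal also appeared in spots made to show none. Of 314 negative control spots, the share marked well above background in the sample channel was 2.55% and 8.60% on the MAPC arrays, 17.8% on ESC replicate 2, and 47.5% and 3.50% on the NS arrays, each above the 0.955% that a count of 0 allows. ESC replicate 1 had 0%. The mark therefore says little about whether a transcript was present, most of all on NS replicate 1, and the cause was not tested.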

How the results depend on the processing

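The filter on the negative controls and the fit of genes with a symbol alone were chosen after the results were seen, and so was the rule that a sign change counts only where a call is involved. The larger direction of the calls stayed in MAPC minus ESC under the settings run. It turned in MAPC minus NS with the processed intensities (7373 higher, 7343 lower), the series matrix (7542 and 7391) and genes with a symbol (3594 and 3264), and in ESC minus NS in the sample channel alone (3514 and 3826), and was level there with the series matrix (6086 each). No scaling moved the median of all genes by more than 0.08 (log2). The number of arrays and, as the negative controls show, the signal over background limit all values, and a group left with 1 array was assumed to vary like the others. Scan date as a term was not run. Leaving out 1 array gave 11488 to 12812 genes between MAPC and ESC, 12966 to 15965 between MAPC and NS and 11335 to 13500 between ESC and NS. The replicate block gave 14184, 16316 and 14157, called Tal1 (MAPC minus ESC) and Kit (ESC minus NS), lost Hoxc9 (MAPC minus NS), and changed no other call on a list or named gene.

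The sample channel alone, from processed intensities scaled to a percentile, gave 7420, 10288 and 7340 genes, with 2038 higher and 2612 lower in MAPC than in both others, and distances of 0.931 (MAPC to ESC), 1.12 (MAPC to NS) and 0.891 (ESC to NS); the cause was not tested. Genes with a symbol alone, with 12150 tested instead of 35771, gave 6296, 6858 and 6349 genes, 1949 and 2015 against both, and distances of 0.809, 0.960 and 0.794. A 2-fold minimum, stricter by construction, gave 3065, 4088 and 3215 genes, and 776 and 915 against both. The MAPC distances to ESC and NS were 0.820 and 0.967 with the deposited processed intensities and 0.806 and 0.951 with the series matrix, which repeats them. Without background subtraction, which compresses ratios by construction, the distances were 0.453, 0.541 and 0.458.

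With an estimated correlation 0 of the 54 list tests passed (lowest adjusted p = 0.0918, with 15 at an unadjusted p under 0.05), against 32 with the preset and 46 with fry. The estimate rests on 3 residual degrees of freedom. Even pluripotency in ESC minus NS, with 22 of 24 genes higher, was not called that way. The 32 stayed called with the replicate block, the processed intensities, offset 16, the series matrix, the other filters, 2 groups at a time and array weights. Without background subtraction 6 were lost, with genes with a symbol alone 5, in the sample channel alone 4, with scale normalization or averaged probes 2 each, and with a trended robust prior 1. Without MAPC replicate 1 the calls lost numbered 2, and 1 each without ESC replicate 1, ESC replicate 2 and NS replicate 2. These were calls on cell cycle, mature blood, hematopoietic, astrocyte, mesenchymal (MAPC minus NS) and MHC class I genes. With fry, astrocyte and oligodendrocyte genes were called upward between MAPC and ESC (median -0.073, adjusted p = 0.0217, against 0.277 to 0.823 in camera over the other settings). Pluripotency in MAPC minus NS gained a call under 6 settings of camera and with fry, and gastrulation in ESC minus NS in the sample channel alone.

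Of 338 values of named genes 317 passed, and no setting left more than 15 of those tested short of the threshold. Apart from the key genes, they were named because they passed with large folds or bounds, so these shares largely follow from the naming rule. Directions reversed for Hoxc6 (-0.10) and Aif1 (-0.055) in MAPC minus NS with scale normalization, for Sox17 (-0.41) in ESC minus NS in the sample channel alone, and with averaged probes for T (-0.32 against ESC, -0.027 against NS) and Lmo2, not called on its brightest probe (-0.26 in MAPC minus NS, -0.22 in ESC minus NS), because their probes differ. Zfp42 in MAPC minus ESC was not called with the processed intensities or the series matrix (-0.25 each). For the others the cause was not tested.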

Other observations

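The tests of gene families and of the Y-linked signals, and the use of planned tests to weigh explanations, were chosen after their results were seen. Families of genes whose symbols share a stem were tested for basic cell functions. Of 579 tests on 193 families of at least 8 members, 40 passed in camera with the preset correlation and 0 with an estimated one (19 at an unadjusted p under 0.05). The calls given next were thus all lost with an estimated correlation (adjusted p from 0.799 to 0.807 for those printed with a camera adjusted p). In ESC minus NS, 11 of 12 nucleoporin genes (Nup) were higher and 1 lower, with a median of 0.85 (camera adjusted p = 0.000500), and all 8 genes of the Mcm family, 6 of them in the cell cycle list too, were higher, with a median of 0.81 (camera adjusted p = 0.000708). The glycosylation genes named Alg were higher in MAPC than in ESC for 8 of 10, with a median of 0.62 (camera adjusted p = 0.00174), and than in NS for 8 of 10, with a median of 0.60 (camera adjusted p = 0.0200). Proteasome genes named Psmd were higher in MAPC than in NS for 9 of 10, with a median of 0.52 (camera adjusted p = 0.00609). Psmd was also called higher in ESC than in NS (median 0.36), and Nup and Mcm higher in MAPC than in NS (medians 0.66 and 0.47). These differences from NS are therefore not particular to 1 of the other cell types. Ribosomal protein genes named Rpl were lower in MAPC than in ESC for 21 of 39 and higher for 2, with a median of -0.25 (camera adjusted p = 0.0152), and against NS their median of -0.28 (camera adjusted p = 0.0482) turned to 0.07 with median centring. Those described were picked from the 40 for their known functions, and apart from Rpl against NS their medians kept their sign under each of the 7 other scalings and background settings tried.

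Fibroblast genes, such as Col1a1, Lox and Postn, stood higher in ESC than in MAPC and NS. Of the 23 measured genes of the mesenchymal list, 0 are in another list. The list's median for MAPC minus ESC was -2.51 in the sample channel alone. Those intensities were already normalized between the dyes, so this value cannot exclude normalization against the reference as a cause. RNA of feeder fibroblasts stays open as a hypothesis: the labels place ESC on such feeders and then plate them without. How far that step removed the feeders was not measured. Hox genes, which embryonic fibroblasts carry, were higher in ESC (camera adjusted p = 0.00415 against MAPC and 0.000118 against NS). These calls were lost with an estimated correlation (adjusted p = 0.282 and 0.217). That estimate rests on 3 residual degrees of freedom and called 0 of 54 list tests, so the loss decides nothing here. Col1a1 stood at 0.19 (log2) relative to the reference pool in ESC, against -2.18 in MAPC and -1.97 in NS. Early differentiation of ESC may act as well: the gastrulation list gave a median of 0.0194 for MAPC minus ESC over members that went both ways, which decides nothing, and later stages were not tested.

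The Y-linked genes Ddx3y, Eif2s3y and Uty were lower in MAPC than in both other cell types. The smallest of these decreases was -1.94 (log2) in the sample channel alone, but those intensities were already normalized between the dyes. Background-subtracted signals, which were not, argue against normalization against the reference for Ddx3y and Eif2s3y. For Ddx3y they were 51.0 and 40.2 in MAPC, 220 and 239 in ESC, and 425 and 471 in NS. For Eif2s3y they were 88.3 and 65.7 in MAPC, 546 and 568 in ESC, and 948 and 1146 in NS. Whether the clone lacks Y-linked transcripts stays open. The number of the 3 genes above the highest negative control spot on both MAPC arrays was 0. Ddx3y (51.0) and Eif2s3y (88.3) exceeded that spot (39.9) on MAPC replicate 1 but not on replicate 2 (40.2 and 65.7 against 165). There they lay above 99.7% of the 314 control spots, and they were well above background on both arrays. Neither result settles the question. Of 797 olfactory receptor probes, 88.7% and 94.4% exceeded the 99th percentile of the control spots on MAPC replicates 1 and 2. The well-above-background mark was carried by 90.3% and 97.9% of them. Uty was not well above background on either array, and binding of related transcripts to these probes was not tested. The sex of the cells is not given in the sources used here.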
